A study of Homo sapiens with 12 samples.

How the data were processed

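Gene expression was measured on 12 Affymetrix-type oligonucleotide arrays with 54675 probe sets. The RNA came from MDA-MB-231 cells, a human breast cancer line that lacks endogenous estrogen receptor alpha (ERα). Per the labels' protocols, cells were infected for 48 h with recombinant adenovirus and then treated with 1 nM estradiol for 6 h, and biotin-labelled cDNA was made from 20 ng of total RNA with an amplification kit (NuGen Ovation). The virus carried either no cDNA (6 arrays, empty vector) or the cDNA of an ERα mutant that the labels describe as unable to bind the estrogen response element (ERE), the DNA motif the receptor recognises (6 arrays, ERα mutant). Each array was placed in its group by its label. The series text describes 6 independent experiments on 6 days, so the arrays of a group were treated as biological replicates.

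The deposited values are intensity values per probe set that the authors had already normalized across arrays. Per the submitters' processing notes they were made with GCRMA, which corrects background from probe sequence, equalises the distributions of the arrays and summarises each probe set. Its version and settings are not given in the sources used here. The values are linear, from 4.38 to 53168, not on the log scale that GCRMA usually returns, so log2(value + 1) was used, as foreseen for that case before the data were examined. Equalised distributions remove any overall shift in RNA amount between the groups. GCRMA also draws dim probe sets to a common floor, where they show little spread. A fold change is on the log2(value + 1) scale and understates the change of dim genes. No 2 arrays held identical values. The number of arrays limits the precision.

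After 62 control probe sets were left out, the comparison covered the 17450 probe sets with a log2 value above 4 (linear 15) on at least 6 of the 12 arrays, 32.0% of those on the array. Probe sets were named from the platform annotation table that came with the data, in which 41097 had 1 gene symbol, 1801 had several and 11777 were not listed. A probe set with several genes, or not listed, was given no gene name. List members without a probe set of 1 gene symbol, AREG, BIRC3 and CSF2 among them, were not counted as measured. Probe sets without a gene name may still measure them. Among the tested probe sets 15224 had 1 gene, 749 had several and 1477 were not listed. Each gene was represented by its brightest probe set over all 12 arrays, which gave 8957 genes, and of the genes named here only CCND1, which did not pass, had another tested probe set of opposite sign.

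Group differences (ERα mutant minus empty vector) were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only, all 12 arrays, statmod 1.5.0), and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. Where every array of a group lay at or below log2 4, the fold is given as a lower limit against log2 4. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 19 lists that had enough measured members. Camera with an estimated correlation, fry and an exact two-sided permutation of the mean of each list per array (924 assignments) were run beside it. The list mean was taken relative to the mean of all tested genes on the same array. Array quality measures were compared by exact permutation.

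The tests and the 21 gene lists were fixed before the data were examined, except that the exact permutation of list means, a 3' to 5' covariate and the replicate block without pair 2 were added after the data had been seen. Tests for a wrong label on mutant replicate 2 and for its part in the interferon difference were also chosen after results were seen. So were the tests of STAT3 and LXR target genes. Leaving out each array in turn, mutant replicate 2 included, was fixed before. The lists were written from textbook knowledge and cover ERE-linked and AP-1/Sp1-linked estrogen genes, immediate early, NF-kB, interferon, DNA replication, mitosis, p53, unfolded protein, heat shock, cholesterol, hypoxia, TGF-beta and YAP, mesenchymal, luminal, coregulator, apoptosis, ribosomal and respiratory chain genes. Markers of haematopoietic and stromal cells and of embryonic kidney cells, the line commonly used to grow adenovirus, completed them. The genes to be named were ESR1, the 14 with the largest rise and the 14 with the largest fall among those that passed, and in each list the 2 members with the smallest p in each direction. Genes named beyond this rule are said to have been chosen after their values were seen.

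The alternatives were the replicate number as a fixed or random block, median centring, quantile normalization, no filter or a stricter filter (mean log2 above 6), values below log2 4 set to 4, a trended robust variance prior, array weights, a pseudocount of 16, other ways to represent a gene, and each array left out in turn. On simulated data with 200 of the 17450 probe sets changed, the 12-array fit recovered 83% of 1.5-fold and 94% of 2-fold changes, with 2.75% false calls. Without mutant replicate 2 it recovered 94% and 97%, with 6.37% false calls. Plots were drawn with matplotlib 3.10.9. Genome positions of the genes were not used here, and untreated cells and the unmutated receptor were not analysed here.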

Results

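The data are 12 arrays of MDA-MB-231 cells treated with 1 nM estradiol for 6 h, 6 from cells infected with empty adenovirus and 6 from cells infected with virus for an ERα mutant that cannot bind EREs. The question is which transcripts differ in estradiol-treated cells when a receptor is present that lacks its usual route to DNA. Median intensity was 5.05 to 5.09 on every array, and 31.9 to 32.1% of probe sets lay above the filter. GCRMA equalises the distributions of the arrays, so this likeness says little about their quality.

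Cells with the ERα mutant had higher levels of the activin-binding protein gene FST (3.69-fold), the matrix metalloproteinase gene MMP3 (3.75-fold), the cytokine gene IL6 (2.55-fold) and the plasminogen activator genes PLAU (2.20-fold) and PLAT (2.13-fold). They had lower levels of the cytokine gene IL11 (2.52-fold lower), the cholesterol efflux transporter gene ABCA1 (2.10-fold lower) and the hyaluronan synthase gene HAS2 (1.92-fold lower). The chemokine gene CXCL1 (1.47-fold) and the interferon-stimulated gene IFIT1 (1.28-fold) were also higher. Of the ERE-linked estrogen-induced genes TFF1, GREB1 and PGR stayed at array background in both groups, while IGFBP4 was 1.26-fold higher.

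ESR1, which encodes ERα and was the introduced gene, checked the labels. Its representative probe set measured 13.05 ± 0.14 on the log2 scale in the mutant group and 2.86 ± 0.17 in the empty-vector group (SD, n = 6), where all 6 arrays were at background, so the level was at least 530-fold higher (limma, Benjamini-Hochberg adjusted p = 5.58e-16). For the 4 other ESR1 probe sets above the filter the level was at least 554-fold, 530-fold, 253-fold and 65.1-fold higher. The remaining 4 of the 9 ESR1 probe sets were below the filter on all 12 arrays. Which part of the transcript they cover is not given in the sources used here.

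**Figure D1:**
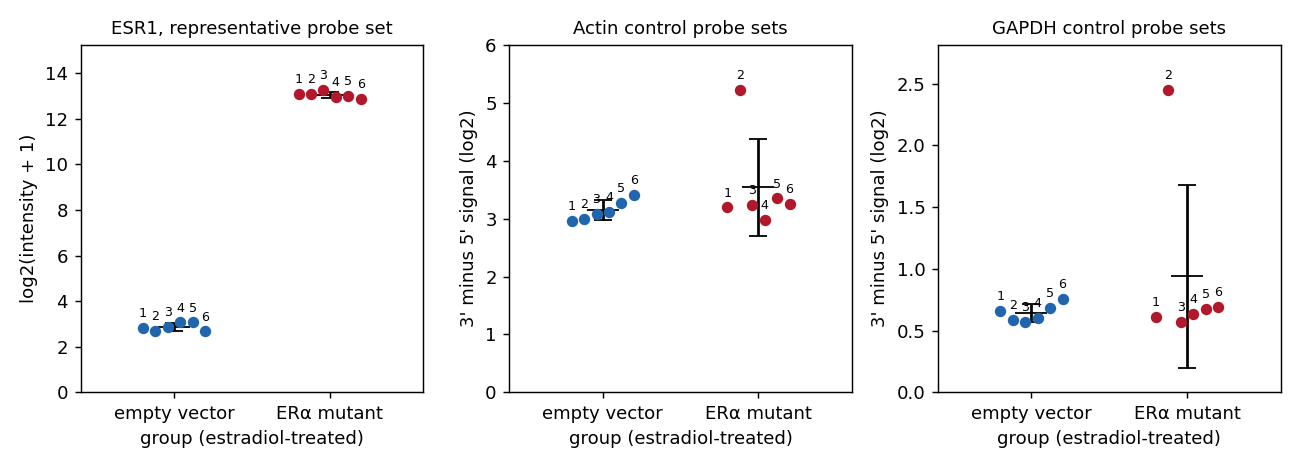
Each point is 1 array, numbered by replicate, with group mean and SD (n = 6), for ESR1 (log2 of intensity + 1) and for the 3' minus 5' signal (log2) of the actin and GAPDH control probe sets. ESR1 separates the groups, and mutant replicate 2 lies apart at 5.22 for actin and 2.45 for GAPDH.

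Of the 17450 probe sets tested, 190 differed between the groups (limma, Benjamini-Hochberg adjusted p under 0.05), 105 higher and 85 lower with the mutant. At least 1.5-fold changes were found for 61 of them, 40 up and 21 down. Counted once per gene, 61 genes rose and 57 fell, 118 of 8957, with a median size of 0.43 on the log2 scale, and 34 of them changed at least 1.5-fold. These counts include the introduced gene ESR1, with 5 probe sets. Mutant replicate 2 stood apart from the other 11 arrays in a measure of RNA quality, with an actin 3' minus 5' signal of 5.22 against 2.97 to 3.42. Without it 440 probe sets (219 up, 221 down) and 264 genes passed, and all 190 earlier probe sets passed with the same sign. The count of genes was 78 without mutant replicate 3, 77 without mutant replicate 5 and 78 without empty-vector replicate 5. With the replicate number as a fixed block 102 probe sets and 59 genes passed, and 13 of the 42 named genes other than ESR1 lost their calls. With no filter 125 probe sets and 75 genes passed, and with array weights 563 and 338. With the 3' to 5' signal as a covariate, added after the data were seen, 423 and 249 passed.

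Among the genes that rose, FST measured 11.51 ± 0.13 against 9.63 ± 0.08 in the empty-vector group (SD, n = 6; log2 difference 1.88, SE 0.064, limma, Benjamini-Hochberg adjusted p = 4.63e-09), and all 3 of its probe sets passed. MMP3 measured 6.87 ± 0.43 against 4.96 ± 0.44 (log2 difference 1.91, SE 0.230, limma, Benjamini-Hochberg adjusted p = 0.00125). PLAU, the urokinase gene, measured 11.19 ± 0.33 against 10.06 ± 0.08, and PLAT, the tissue-type activator gene, 8.24 ± 0.42 against 7.15 ± 0.22. Their limma adjusted p-values (Benjamini-Hochberg) were 0.0008 and 0.00936. CEMIP, whose product binds and helps degrade hyaluronan, rose 2.52-fold, and TGFBI, which encodes a matrix protein, rose 1.75-fold. The growth factor gene NRG1 rose 1.67-fold and the gap junction gene GJB2 1.78-fold. SYNJ2, a phosphoinositide phosphatase gene, rose 1.97-fold, and ABTB2 and ZFPM2, the latter encoding a cofactor of GATA factors, rose 2.37-fold and 1.92-fold. The other tested probe sets of NRG1 and SYNJ2, with log2 differences of 0.8 and 0.695, did not pass. SHOC1, a gene known from meiotic recombination, was at background on all 6 empty-vector arrays and at least 2.42-fold higher with the mutant. In each of these genes, and in IL6, all 6 mutant arrays lay above every empty-vector array. The calls of ABTB2 and ZFPM2 were lost with 9 and 8 of the 12 arrays left out in turn (limma, Benjamini-Hochberg adjusted p up to 0.0934 and 0.0791). With no filter these 2 calls and those of NRG1 and PLAT were lost (limma, Benjamini-Hochberg adjusted p = 0.181, 0.156, 0.0889 and 0.0606).

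Among the genes that fell, IL11 measured 5.63 ± 0.16 with the mutant and 6.97 ± 0.45 with empty vector (SD, n = 6; log2 difference -1.33, SE 0.180, limma, Benjamini-Hochberg adjusted p = 0.00281). ABCA1 measured 7.68 ± 0.27 against 8.75 ± 0.15 (log2 difference -1.07, SE 0.117, limma, Benjamini-Hochberg adjusted p = 0.0006). HAS2, which encodes an enzyme that makes hyaluronan, measured 8.03 ± 0.21 against 8.97 ± 0.22, with a limma adjusted p of 0.0016 (Benjamini-Hochberg). Its other tested probe set had a log2 difference of -0.539 and did not pass. The cytokine gene IL24 was 1.78-fold lower and the atypical chemokine receptor gene CCRL2 1.86-fold lower. POU2F2, an octamer-binding transcription factor gene, was 1.70-fold lower, and all 4 of its probe sets passed. LFNG, which encodes a glycosyltransferase that modifies Notch receptors, was 1.53-fold lower, and TXNIP, which encodes a thioredoxin-binding protein, 1.78-fold lower. The atypical cadherin gene FAT3 was 2.24-fold lower, the histone gene H2BC21 1.74-fold lower and IL1RAPL1 1.59-fold lower. Histone genes of this family are close in sequence, so the H2BC21 value is uncertain. NANOS1, an RNA-binding repressor gene, and PEAR1 were 2.32-fold and 1.84-fold lower. Their calls were lost with 10 and 9 of the 12 arrays left out in turn (limma, Benjamini-Hochberg adjusted p up to 0.0733 and 0.0921). With no filter the calls of NANOS1, PEAR1 and TXNIP were lost (limma, Benjamini-Hochberg adjusted p = 0.145, 0.171 and 0.0667), and with the median of a gene's probe sets that of TXNIP (limma, Benjamini-Hochberg adjusted p = 0.220). In all 14 genes of this group, CCN2 included, the 6 mutant arrays lay below every empty-vector array.

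**Figure D2:**
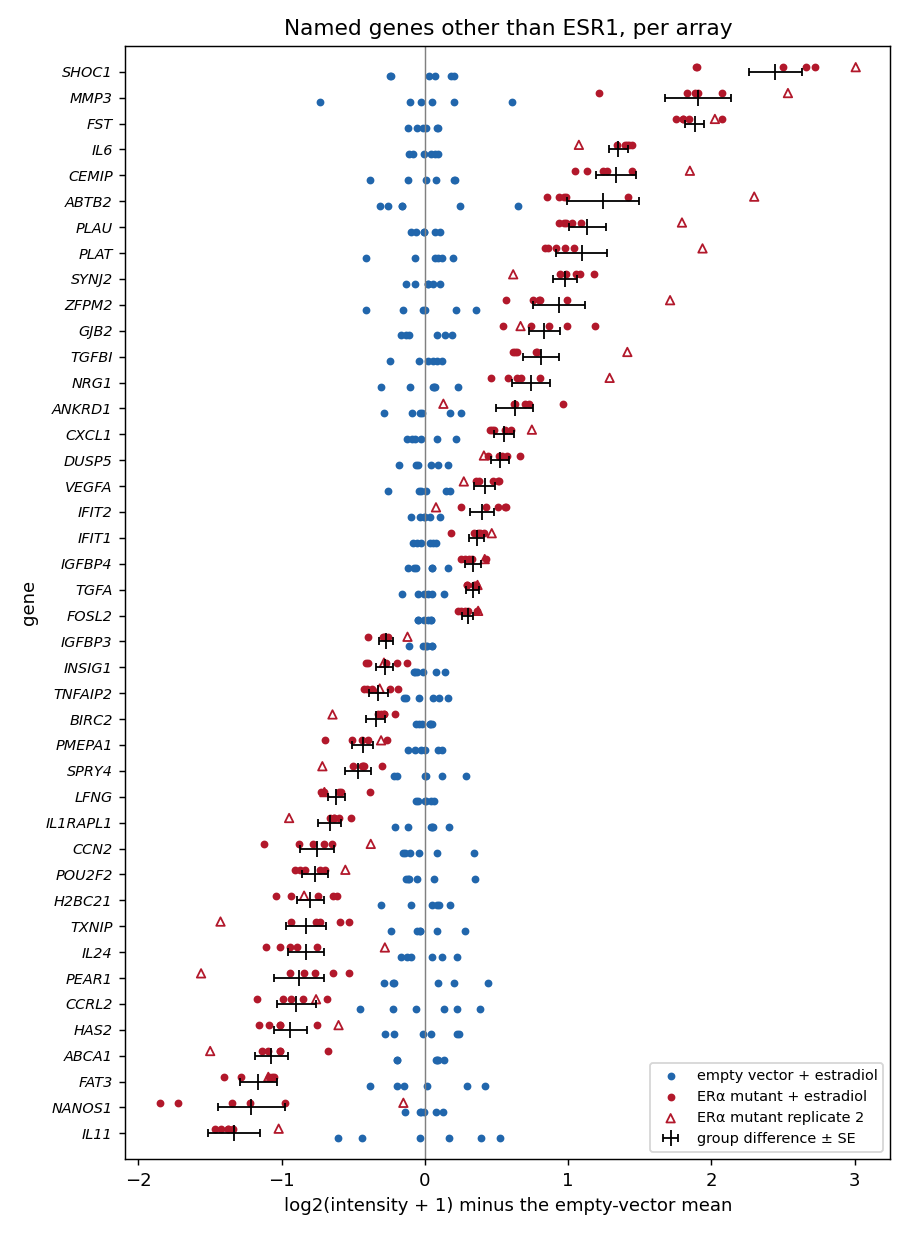
Log2(intensity + 1) of each array minus the empty-vector mean for 42 named genes other than ESR1, with the group difference and its SE (n = 6 per group, mutant replicate 2 as a triangle). MMP3 differed by 1.91 and IL11 by -1.33, while for SHOC1, at background on all 6 empty-vector arrays, the values support a difference of at least 1.27.

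NF-kB and inflammatory genes contained 5 members that rose and 1 that fell among 15 measured, the same counts as when adjusted over the list alone. No probe set carried BIRC3 or CSF2 as its 1 gene symbol, so neither was counted and whether they changed is not known here. Probe sets that are unlisted or carry several genes may measure them. IL6 measured 9.08 ± 0.14 against 7.73 ± 0.08 (SD, n = 6; log2 difference 1.35, SE 0.067, limma, Benjamini-Hochberg adjusted p = 2.71e-07). The neutrophil-attracting chemokine gene CXCL1 rose 1.47-fold (limma, Benjamini-Hochberg adjusted p = 0.00164). CXCL8, CXCL2 and CXCL3, named after their values were seen, rose 1.44-fold, 1.35-fold and 1.36-fold (limma, Benjamini-Hochberg adjusted p = 0.0041, 0.0493 and 0.0211). The CXCL2 and CXCL3 calls were lost with 10 and 7 of the 12 arrays left out in turn (limma, Benjamini-Hochberg adjusted p up to 0.117 and 0.0599) and with no filter (0.201 and 0.0889), that of CXCL2 also with median centring (0.0503), quantile normalization (0.0533) and the covariate (0.0520), and that of CXCL8 with the median of a gene's probe sets (0.0565) and without x_at probe sets (0.509). CXCL1, CXCL2 and CXCL3 are close in sequence, so their separate values are uncertain. TNFAIP2 fell 1.25-fold, but lost its call with 8 of the 12 arrays left out in turn (limma, Benjamini-Hochberg adjusted p up to 0.0929) and with no filter (limma, Benjamini-Hochberg adjusted p = 0.114). NFKBIA and TNFAIP3, inhibitors that the pathway induces, had log2 differences of -0.01 and -0.02 and did not pass. The list as a whole was higher (limma's camera, Benjamini-Hochberg adjusted p = 0.00632; exact permutation adjusted p = 0.0206), with a mean log2 difference of 0.22 and a median of 0.01. With the estimated correlation, 0.146 against the preset 0.01, the adjusted p was 0.589 (limma's camera, Benjamini-Hochberg), so the preset value overstates the evidence. Without probe sets of the x_at type, which can bind related transcripts, the adjusted p was 0.140 at the preset correlation (limma's camera, Benjamini-Hochberg).

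Interferon-stimulated genes were higher as a group, with a median log2 difference of 0.28 over 14 measured members, of which 13 had a positive difference. The list passed at the preset correlation of 0.01 (limma's camera, Benjamini-Hochberg adjusted p = 2.46e-09, exact permutation adjusted p = 0.0206). It did not pass at the estimated correlation of 0.333 (limma's camera, Benjamini-Hochberg adjusted p = 0.271). The camera p at the preset correlation therefore overstates the evidence. Of 100 splits of the 12 arrays into 6 and 6, the real one included, 28 gave 3 or more passing lists. IFIT1 measured 10.13 ± 0.10 against 9.77 ± 0.07 (SD, n = 6; log2 difference 0.36, SE 0.052, limma, Benjamini-Hochberg adjusted p = 0.0041). IFIT2 rose 1.32-fold (limma, Benjamini-Hochberg adjusted p = 0.0386), a call lost with 10 of the 12 arrays left out in turn, at adjusted p up to 0.108, and also with no filter (0.156). These 2 genes passed over all probe sets, and 11 passed when adjusted over the list alone. The viral RNA sensor gene IFIH1 had a log2 difference of 0.45 and did not pass over all probe sets (limma, Benjamini-Hochberg adjusted p = 0.0729). Another 17 members, MX1, OAS1 and IFI6 among them, were below the filter. Without mutant replicate 2, the array with the high 3' minus 5' signal, 3 members passed over all probe sets, the median was 0.22 and the exact permutation adjusted p 0.0206.

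ERE-linked estrogen-induced genes had 21 measured members, of which 1 rose and none fell. The list did not pass as a whole (limma's camera, Benjamini-Hochberg adjusted p = 0.221) and had a median log2 difference of 0.04. IGFBP4, which encodes an insulin-like growth factor binding protein, was the member that rose, from 11.03 ± 0.10 to 11.37 ± 0.07 (SD, n = 6; 1.26-fold, limma, Benjamini-Hochberg adjusted p = 0.00883). Its call was lost with the replicate number as a fixed block (limma, Benjamini-Hochberg adjusted p = 0.0677). Adjusted over the list alone 2 members passed, the other being MYB, with a log2 difference of 0.62 and a limma adjusted p of 0.102 over all probe sets (Benjamini-Hochberg), or 0.00877 without mutant replicate 2, when 2 members passed over all probe sets. Another 16 members were below the filter. No probe set carried AREG as its 1 gene symbol, so it was not counted and whether it changed is not known here. A probe set that is unlisted or carries several genes may measure it. TFF1 measured 2.55 in both groups, GREB1 2.60 and 2.61, and PGR 2.55 in both, so a difference in these genes was not detectable here. Fry, which asks whether members move one way on balance, gave an adjusted p of 0.0161 for this list (limma, Benjamini-Hochberg).

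Of 15 measured AP-1/Sp1-linked estrogen-responsive genes, which are linked to receptor action through other DNA-bound factors, 2 rose and 1 fell. TGFA, an EGF receptor ligand gene, rose 1.26-fold and VEGFA, the angiogenic factor gene, 1.34-fold, while IGFBP3 fell 1.21-fold (limma, Benjamini-Hochberg adjusted p = 0.00408, 0.0162 and 0.0164). The calls of TGFA and IGFBP3 were lost with the median of a gene's probe sets (limma, Benjamini-Hochberg adjusted p = 0.733 and 0.186). They were also lost with the replicate number as a fixed block (limma, Benjamini-Hochberg adjusted p = 0.0557 and 0.115). The VEGFA call was lost with no filter (limma, Benjamini-Hochberg adjusted p = 0.0641), and its other tested probe set, with a log2 difference of 0.483, did not pass. Adjusted over the list alone, 2 rose and 2 fell. CCND1 and MYC had log2 differences of -0.02 and 0.31 and did not pass. Among 22 measured AP-1 and immediate early genes, DUSP5 and FOSL2 rose 1.44-fold and 1.23-fold, and CCN2 and SPRY4 fell 1.69-fold and 1.38-fold. DUSP5 encodes a phosphatase of ERK kinases and FOSL2 an AP-1 subunit. The SPRY4 call was lost with 8 of the 12 arrays left out in turn (limma, Benjamini-Hochberg adjusted p up to 0.0821) and with no filter (limma, Benjamini-Hochberg adjusted p = 0.135). The FOSL2 call was lost with the median of a gene's probe sets (limma, Benjamini-Hochberg adjusted p = 0.168). Adjusted over the list alone, 2 rose and 4 fell. Without mutant replicate 2, 3 rose and 4 fell over all probe sets, and 6 rose and 7 fell over the list alone. Neither list passed as a whole (limma's camera, Benjamini-Hochberg adjusted p = 0.221 for each; exact permutation adjusted p = 0.196 and 0.0514).

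**Figure D3:**
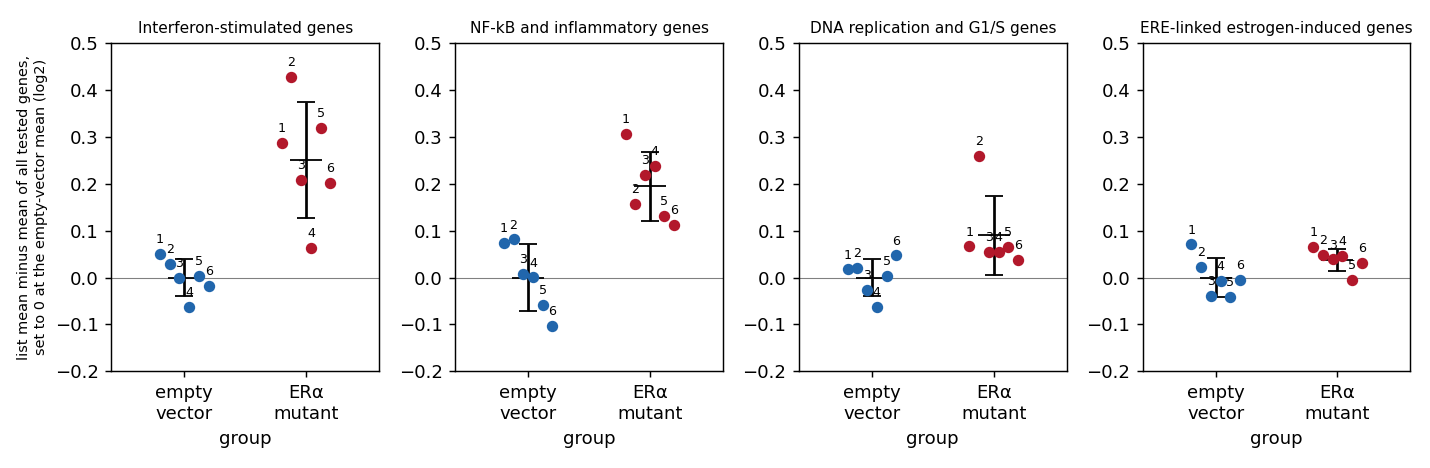
Mean of each list per array relative to all tested genes (log2), set to 0 at the empty-vector mean, for 4 gene lists, with group mean and SD (n = 6) and replicate numbers. The group difference is 0.25 for interferon-stimulated genes, 0.19 for NF-kB genes, 0.09 for DNA replication genes, where mutant replicate 2 lies apart, and 0.04 for ERE-linked genes.

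DNA replication and G1/S genes had a median log2 difference of 0.13 over 31 measured members, 28 of them positive, and 0.05 without mutant replicate 2. The list passed at the preset correlation of 0.01 (limma's camera, Benjamini-Hochberg adjusted p = 0.00509, exact permutation adjusted p = 0.0274). It did not pass at the estimated correlation of 0.187 (limma's camera, Benjamini-Hochberg adjusted p = 0.589), so the camera p at the preset correlation overstates the evidence. No member passed limma's test over all probe sets or when adjusted over the list alone, and 6 had an unadjusted p under 0.05. The largest difference over all 12 arrays, 0.29, was that of MCM3, a subunit of the replicative helicase. Without mutant replicate 2 the MCM3 difference was 0.105, and those of E2F2 (0.308) and GINS1 (0.301) were larger. Mutant replicate 2 had a list mean of 1.25 against 1.03 to 1.06 on the other mutant arrays. Without it the exact permutation adjusted p was 0.0514, and 1 member rose when adjusted over the list alone. G2/M and mitosis genes (32 measured, median 0.02) and p53 targets (18 measured, median -0.02) had no member that passed, over all probe sets or adjusted over the list alone, and limma camera adjusted p-values of 0.759 and 0.619 (Benjamini-Hochberg). At an unadjusted limma p under 0.05 they had 1 and 2 members. Among 21 measured apoptosis regulators BIRC2, an inhibitor of apoptosis gene, fell 1.27-fold and none rose, also when adjusted over the list alone (limma's camera, Benjamini-Hochberg adjusted p = 0.875), where without mutant replicate 2 there were 2 that rose and 1 that fell. The BIRC2 call was lost with 9 of the 12 arrays left out in turn (limma, Benjamini-Hochberg adjusted p up to 0.0712) and with no filter (limma, Benjamini-Hochberg adjusted p = 0.0889).

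TGF-beta and YAP target genes changed in both directions. Of 23 measured, TGFBI and ANKRD1 rose 1.75-fold and 1.54-fold, and CCN2 and PMEPA1 fell 1.69-fold and 1.35-fold. Adjusted over the list alone 3 rose and 4 fell. The list's limma camera adjusted p was 0.908 (Benjamini-Hochberg), in the downward direction although the median was 0.06. The ANKRD1 call was lost with 10 of the 12 arrays left out in turn (limma, Benjamini-Hochberg adjusted p up to 0.0945) and with no filter (limma, Benjamini-Hochberg adjusted p = 0.177). The PMEPA1 call was lost with the replicate number as a fixed block (limma, Benjamini-Hochberg adjusted p = 0.0693) and with that block without pair 2 (0.0647). The other tested PMEPA1 probe set, with a log2 difference of -0.355, did not pass. Of 18 mesenchymal and basal genes PLAU rose, and adjusted over the list alone 2 rose and 2 fell (limma's camera, Benjamini-Hochberg adjusted p = 0.824). Without mutant replicate 2, 2 rose and 2 fell over all probe sets. Of 24 hypoxia and glycolysis genes VEGFA rose, and adjusted over the list alone 3 rose and 2 fell (limma's camera, Benjamini-Hochberg adjusted p = 0.908, median -0.01, mean 0.004, direction down). Without mutant replicate 2, 3 rose and 2 fell over all probe sets, and 5 rose and 2 fell over the list alone.

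Among 19 measured cholesterol synthesis genes INSIG1, which encodes a sterol-sensing regulator, fell 1.21-fold, a call lost with 10 of the 12 arrays left out in turn (limma, Benjamini-Hochberg adjusted p up to 0.126) and with no filter (limma, Benjamini-Hochberg adjusted p = 0.141). Adjusted over the list alone 2 fell, as did 2 over all probe sets without mutant replicate 2. The list did not pass (limma's camera, Benjamini-Hochberg adjusted p = 0.140), but did at 0.0194 without mutant replicate 2, at 0.0424 without mutant replicate 1 and at 0.0384 without empty-vector replicate 5. The unfolded protein (22 measured), heat shock (14), ribosomal protein (25), respiratory chain (27) and nuclear receptor coregulator (22) lists had no member that passed, over all probe sets or adjusted over the list alone, and 2, 0, 0, 0 and 2 members at an unadjusted limma p under 0.05. Without mutant replicate 2, 1 heat shock and 2 coregulator genes rose when adjusted over the list alone. Their limma camera adjusted p-values (Benjamini-Hochberg) were 0.619, 0.619, 0.221, 0.619 and 0.824. The unfolded protein list had a median of 0.005 and a mean of -0.01, with a downward direction. The heat shock list's mean relative to all tested genes was -0.002, against an upward direction in camera. Probe sets shared by HSPA1A and HSPA1B, members of that list, rose but were not counted in it, as given below.

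Besides the named genes, 3 probe sets that the annotation assigns to both HSPA1A and HSPA1B, 1 of them also to HSPA1L, rose. Their log2 differences were 1.57, 1.17 and 0.64 (limma, Benjamini-Hochberg adjusted p = 0.000587, 0.000102 and 0.00251). These genes are members of the heat shock list, but the 3 probe sets were not counted in it because each carries more than 1 gene. The result of that list therefore leaves them out. A probe set assigned to both KRTAP2-3 and KRTAP2-4 had a log2 difference of -1.55, a larger fall than that of IL11 (limma, Benjamini-Hochberg adjusted p = 0.000176). Of the 190 probe sets, 172 had 1 gene, 6 had several (4 up, 2 down) and 12 were not listed (8 up, 4 down). The genes of the unlisted probe sets were not identified here, so list members not counted as measured may be among them. Of the unlisted probe sets that rose, 1 measured 9.97 ± 0.08 against 8.54 ± 0.15 (SD, n = 6; limma, Benjamini-Hochberg adjusted p = 1.94e-07) and another 7.29 ± 0.49 against 5.87 ± 0.22 (limma, Benjamini-Hochberg adjusted p = 0.00399).

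Luminal breast markers had 10 measured members, none of which passed limma's test over all probe sets (3 had an unadjusted p under 0.05), and 1 that rose when adjusted over the list alone (limma's camera, Benjamini-Hochberg adjusted p = 0.824) and, without mutant replicate 2, over all probe sets. All 18 haematopoietic and stromal markers on the array were below the filter. Of 14 embryonic kidney cell markers on the array, GATA2 was measured, with a log2 difference of -0.16 that did not pass (limma, Benjamini-Hochberg adjusted p = 0.750). The group difference in the 3' minus 5' signal did not pass an exact permutation test (actin p = 0.262, GAPDH p = 0.554; 7 array measures compared, Benjamini-Hochberg adjusted p = 0.753 and 0.776). Both groups received estradiol, so the comparison describes the mutant receptor with hormone against no introduced receptor with hormone, and it does not separate the effect of the hormone from that of the protein.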

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

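The tests for a wrong label on mutant replicate 2 and for the part of this array in the interferon difference were chosen after the result was seen.

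All 11 values that stood apart from the other arrays of their group belonged to mutant replicate 2, among 104 groups of 6 tested, where chance gives about 5.2. A value was taken to stand apart where its gap to the nearest array, as a share of the group's range, exceeded the critical value of Dixon's test. For the 3' minus 5' signal the gap was 0.834 of the range for actin and 0.936 for GAPDH. Among genes it was 0.823 for PLAU, 0.814 for PLAT, 0.793 for TGFBI, 0.632 for ZFPM2, 0.72 for IL6, 0.724 for IL11, 0.653 for IL1RAPL1 and 0.733 for BIRC2. PLAU measured 11.85 on this array against 10.99 to 11.14 on the other mutant arrays, whereas IL6 measured 8.81 against 9.08 to 9.18. The mean of the DNA replication and G1/S genes had a gap of 0.872 of the range.

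Mutant replicate 2 correlated with the other arrays at 0.963 to 0.970, while those correlated with one another at 0.992 to 0.998. A wrong label is argued against by ESR1, which lay 10.04 log2 units above the highest empty-vector array. On this array the 3' control signals lay within the range of the other arrays (actin 41282 against 38895 to 41693, GAPDH 14517 against 14467 to 15817). The 5' signals lay below that range (actin 1104 against 3904 to 5065, GAPDH 2657 against 8647 to 10431). Shortened RNA would give such a loss of 5' signal, but it cannot be told apart from other faults. The test written for it was the correlation between the deviations of 2 probe sets of a gene over 3836 genes. It gave r = 0.241 on this array and 0.146 to 0.1997 on the other mutant arrays, all on the side taken beforehand to mean shortened RNA. Of 628 genes with a deviation over 1 log2 unit, 36.9% had 2 probe sets that moved in opposite directions. A hybridization fault cannot be told apart, since the hybridization controls lay 0.124 log2 units beyond the range of the other arrays, and no biological explanation was tested.

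The group difference itself did not rest on this array, because 100% of the 190 probe sets passed without it. Of 100 splits of the 12 arrays into 6 and 6, from 462 possible, only the real one (1 of 100) gave as many probe sets (190, highest other 1). The same held for those changed at least 1.5-fold (61, 1 of 100, highest other 0) and for genes (118, 1 of 100, highest other 1). Chance is thus argued against for these counts, which include ESR1, although 1 of 100 is the smallest share these splits can give. The splits took no account of replicate numbers. For the number of gene lists passing camera chance cannot be excluded, since 28 of the 100 splits gave 3 or more lists and the highest other gave 5.

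Interferon-stimulated genes were higher with the mutant by a small amount. The RNA quality of mutant replicate 2 does not account for this, as the median log2 difference without it was 0.22. Members that vary together from array to array are argued against as the whole cause by the exact permutation of the list mean (two-sided p = 0.00216, the smallest the exchanges of array labels can give), although with an estimated correlation the list did not pass (limma's camera, Benjamini-Hochberg adjusted p = 0.271). An effect of the mutant receptor may underlie the difference, but a difference in virus dose or in the cells' response to an inserted cDNA was not tested and stays open.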

How the results depend on the processing

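The replicate block without pair 2, the 3' to 5' covariate and the exact permutation of list means were chosen after seeing the data. No result that passed turned its direction. The 190 probe sets, 118 genes and 3 gene lists became 102, 59 and 3 with the replicate block, 125, 75 and 5 with no filter, 563, 338 and 4 with array weights, 423, 249 and 4 with the covariate, and 288, 165 and 4 with the block without pair 2. With no filter more probe sets share the adjustment, and the variance prior was also refitted over all of them. Which of these lowered the counts of probe sets and genes was not tested, nor was the cause of the other changes. Same-numbered arrays had correlated deviations above 0.1 in 3 of 6 pairs, and 6 of 12 arrays correlated best with their own number (5 of 5 pairs and 8 of 10 arrays without pair 2). The block may thus be part of the design. The series text gives 6 days and both groups carry numbers 1 to 6, but the labels do not say that a number is a day. With single arrays left out, probe sets ranged from 133 to 440, those changed at least 1.5-fold from 54 to 75, genes from 77 to 264, gene lists from 3 to 4 and the ESR1 log2 difference from 10.14 to 10.23.

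Gene lists passing numbered 0 with an estimated correlation (1 at an unadjusted p under 0.05; fry 3, exact permutation 3) and 9 with fry's mixed test. Adjusted p-values below are limma's, with Benjamini-Hochberg. Cholesterol genes passed with no filter (0.00559), array weights (0.0116), the block without pair 2 (0.0466), the covariate (0.0282) and fry mixed (0.0469), and ranged from 0.0194 to 0.353 with arrays left out. Ribosomal genes passed with no filter (0.0134). With an estimated correlation interferon genes were at 0.271, NF-kB genes at 0.589 and DNA replication genes at 0.589. NF-kB genes were at 0.140 without x_at probe sets, and DNA replication genes at 0.133 with fry and 0.112 with fry mixed. ERE-linked genes passed with fry (0.0161) and fry mixed (0.00706). Fry mixed, which counts changes in either direction, also passed AP-1/Sp1-linked (8.38e-08), immediate early (2.14e-10), hypoxia (7.23e-06), TGF-beta and YAP (6.0e-06) and mesenchymal genes (1.88e-05).

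Of 580 refits of the 42 named genes 545 passed, and of 504 with an array left out 413 passed, with 0 reversed in either set. Gene lists changed sign in 36 cases, passing in neither setting. The replicate block ended 13 calls (ABTB2, ANKRD1, BIRC2, IFIT2, IGFBP3, IGFBP4, INSIG1, NANOS1, NRG1, PMEPA1, SPRY4, TGFA and ZFPM2), no filter 14, the block without pair 2 ended 4 (INSIG1, PMEPA1, SPRY4 and ZFPM2) and the median of a gene's probe sets 4. Of the genes chosen after their values were seen, the block ended the calls of EPAS1, EREG, GATA6, IRS1, LEF1, LPIN1, NAMPT, PTGES, RCAN1 and WWTR1, and the block without pair 2 those of EREG, NAMPT and RCAN1. Signal at the background floor limits what can be said of genes below the filter.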

Other observations

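The genes in the next 2 paragraphs were chosen after their values were seen, and the STAT3 and LXR lists below were tested because IL6 and ABCA1 had changed.

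Several regulators and ligands beyond the fixed lists changed by small amounts. SMAD3, which encodes a transducer of TGF-beta signals, measured 12.86 ± 0.06 with the mutant and 12.35 ± 0.04 with empty vector (SD, n = 6; limma, Benjamini-Hochberg adjusted p = 2.82e-05). WWTR1, which encodes the transcriptional coactivator TAZ, rose 1.25-fold, while AJUBA, an adaptor gene of the same Hippo pathway, fell 1.27-fold and VGLL3, a TEAD cofactor gene, fell 1.29-fold. The EGF-family ligand gene EREG rose 1.49-fold (limma, Benjamini-Hochberg adjusted p = 0.00583), beside NRG1 and TGFA. The transcription factor genes FOXQ1, GATA6 and EPAS1 rose 1.56-fold, 1.47-fold and 1.39-fold, and LEF1 rose 1.28-fold. IRS1, an insulin receptor substrate gene, rose 1.20-fold. The calls of GATA6 and LEF1 were lost with no filter (limma, Benjamini-Hochberg adjusted p = 0.108 and 0.0921) and with 2 and 8 of the 12 arrays left out in turn (limma, Benjamini-Hochberg adjusted p up to 0.0628 and 0.0712), and that of WWTR1 with the median of a gene's probe sets (limma, Benjamini-Hochberg adjusted p = 0.541). No pathway was tested for these genes.

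Among genes that fell, SLC7A11, the cystine transporter gene, was 1.33-fold lower (limma, Benjamini-Hochberg adjusted p = 0.000365), and DOCK4, which encodes an activator of small GTPases, 1.34-fold lower (limma, Benjamini-Hochberg adjusted p = 0.000342). The cytokine receptor gene IL7R was 1.36-fold lower, LPIN1, a phosphatidate phosphatase gene, 1.43-fold lower, and the vitamin D receptor gene VDR 1.33-fold lower. NAMPT, an enzyme gene of NAD synthesis, was 1.18-fold lower and the calcineurin regulator gene RCAN1 1.18-fold lower. PTGES, the prostaglandin E synthase gene, and ADAMTS1, a matrix protease gene, rose 1.46-fold and 1.55-fold. LPIN1, VDR, NAMPT and PTGES lay near the threshold (limma, Benjamini-Hochberg adjusted p = 0.0438, 0.0380, 0.0315 and 0.0239). Their calls were lost with no filter (limma, Benjamini-Hochberg adjusted p = 0.191, 0.156, 0.0590 and 0.116) and with 8, 10, 9 and 5 of the 12 arrays left out in turn (limma, Benjamini-Hochberg adjusted p up to 0.118, 0.0979, 0.0856 and 0.0703). With the median of a gene's probe sets those of SLC7A11, NAMPT and RCAN1 were lost (limma, Benjamini-Hochberg adjusted p = 0.202, 0.434 and 0.0583).

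Since IL6 signals through STAT3, a rise of STAT3 target genes was a hypothesis to test. Over 18 measured targets the median log2 difference was -0.02 and VEGFA alone passed (limma's camera p = 0.878; exact permutation p = 0.996; Benjamini-Hochberg over 2 lists 0.878 and 0.996). ABCA1 is a target of the LXR receptors, and 7 other measured targets had a median of -0.03 with none passing (limma's camera p = 0.336; exact permutation p = 0.359; Benjamini-Hochberg over 2 lists 0.673 and 0.719). The bounds written beforehand would have ruled both out: a median under 0.05 in size with a camera p of 0.05 or more, met by both lists, or the opposite direction in camera, met by the STAT3 list. They were set aside after the result was seen, because members went both ways (8 of 18 STAT3 targets and 2 of 7 LXR targets had a positive difference) and a direction at a limma camera p of 0.878 does not stand out from chance. Neither hypothesis gained support, and neither can be excluded.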
